A study of Bos taurus with 3 samples.

How the data were processed

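Single-cell RNA sequencing (10x Genomics 3' v3.1 chemistry, per the labels' protocols) was made of primary cultures of mesenchymal stromal cells (MSCs) grown from adipose tissue, bone marrow and peripheral blood of 1 healthy cow in its opening lactation. Each tissue gave 1 library, so the 3 libraries share a donor and no tissue has a replicate. Cultures were grown in low-glucose DMEM with 30% fetal bovine serum and harvested once colonies could be seen. The deposited values are counts: whole numbers of unique molecular identifiers (UMIs) per gene and barcode, which the authors obtained with Cell Ranger. The version is 6.1.1 per the submitters' processing notes and 4 per the file headers, and it was not settled which of them made the matrices. The genome build is ARS-UCD1.2 per the submitters' processing notes. The matrices hold no coordinates, and none are given.

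The matrices listed 21861 genes and between 1472552 and 2479370 barcodes per library, so they had not been reduced to cells. Of the genes, 17282 carried a symbol and 4579 an Ensembl identifier alone. A RefSeq gene table of another assembly, ARS-UCD2.0, matched 0 of those identifiers, so they are named by identifier. Where 2 genes shared a symbol, the identifier was joined to it. Members of near-identical families (histones, class I and class II antigen-presenting genes, CXC chemokines) can share reads, and their counts are uncertain to that degree, since the counting rule for such reads is not given in the sources used here.

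Barcodes were called cells by an order-of-magnitude rule: a UMI total of at least the 99th percentile of the top 3000 barcodes divided by 10. The resulting thresholds were 4438.5 UMIs for adipose tissue, 4414 for bone marrow and 7489 for blood. Cells with fewer than 500 genes or over 20% mitochondrial UMIs were to be removed, and 0 cells met either limit. Doublets were scored with Scrublet in scanpy 1.11.5 (expected rate 6%). It called 0 of 18561 cells, which for this many cells means that the caller did not work, so doublets were not removed.

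Each library was clustered alone (10000 UMIs per cell, log scale, 2000 variable genes, 30 principal components, 15 neighbours, Leiden resolution 0.5, seed 1). Clusters were called by the markers of 13 cell classes. A class needed at least 3 of its markers among the 50 genes of largest fold, and a cluster whose cells also held at least 0.5 of the library's median share of stromal-marker UMIs was called mixed. Other clusters were called stromal-like where at least 3 stromal markers reached 50 CPM and no other class had more markers than stroma among the 10 leading genes. Clusters that failed either condition were left unnamed.

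Tissues were compared on UMIs summed over the kept cells of a library and expressed as CPM, the UMIs of a gene scaled to a common library total. With 1 library per tissue there is no test, p-value or standard error. A gene counted as apart when the ratio of CPM was at least 2 and the higher library had at least 50 CPM. Ratios carry exact 95% intervals from the UMI counts, and shares of cells carry exact Clopper-Pearson intervals; both cover counting error only. For a count of 0, the upper limit is 3 counts of the total. Ratios against 0 UMIs were set against 3 counts per library and are approximate lower bounds. For 36 gene lists (749 of 793 entries found by symbol), the median log2 ratio was taken over members with at least 10 CPM summed over the pair, for lists with at least 3 such members. It was set against 10000 random lists of the same size, matched on mean expression in 20 bins, and outside their central 95% a list was said to stand apart, as a description of these libraries. Shares of cells with a UMI were computed after thinning each cell to 3000 UMIs, which all kept cells exceeded; at 6000 UMIs, 151 adipose cells, 946 bone marrow cells and 0 blood cells were too shallow and left out. Barcodes of 10 to 100 UMIs served as the profile of free RNA.

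The lists, the markers, these rules and the rule for naming genes were fixed before the data were examined. Named genes are, per pair of tissues, the 10 largest ratios in each direction among genes with a symbol, of at least 100 CPM in the higher library, that are neither mitochondrial nor ribosomal protein genes. Per tissue they are the 10 largest ratios over the higher of the other libraries. They include the 5 leading genes of each cluster, the list members at least 2-fold apart, and THY1, NT5E, ENG, CD44, ITGB1, PTPRC, CD34 and CD14. Other genes named as the highest member of a list, or within the macrophage-like cells, were chosen after their values were seen. The rule also names genes that are not given in the text, where a list or cluster is summarised by some of its members.

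The calculations were tested on simulated counts for the 21861 genes. In each of the 3 pairs, 200 of 200 genes simulated at 3-fold and 0 of 200 at 1.5-fold were counted, and 0 unchanged genes were counted. The simulated counts held counting error alone, and the changed genes lay well above 50 CPM. This checks the calculation and cannot measure how often cultures differ without a tissue effect. Among lists simulated without change, 1 of 21 stood apart between adipose tissue and bone marrow, 4 of 21 between adipose tissue and blood, and 1 of 22 between bone marrow and blood, so a list standing apart by a small median carries little weight.

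Alternatives fixed in advance were TMM factors (edgeR 4.0.16, R 4.3.3), CPM without mitochondrial and ribosomal protein genes, a minimum of 10 CPM, no minimum but 4 UMIs, all barcodes of at least 1000 UMIs, at most 10% mitochondrial UMIs, doublet calls kept, thinning before summing, stromal-like clusters alone, G1-phase cells alone, removal of 10% of UMIs in the proportions of free RNA, 10000 expected cells, thinning to 1500 or 6000 UMIs or not at all, and resolutions of 1.0 and 0.2. Alternatives chosen after seeing the data were the exclusion of macrophage-like, mixed and endothelial-like clusters (the cells left are called the remaining cells), the same with TMM factors, removal of the highest 6% of Scrublet scores, and macrophage shares over all barcodes of at least 1000 UMIs. Other software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and igraph 0.11.9.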

Results

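Mesenchymal stromal cells are spindle-shaped, plastic-adherent cells that can be grown from many tissues and are studied in cattle for veterinary therapy. Cultures from adipose tissue, bone marrow and peripheral blood of 1 Holstein-Friesian cow were profiled by single-cell RNA sequencing, with 1 library per tissue. The question was how the source tissue goes with the composition and expression of donor-matched cultures. No tissue had a replicate, so the values below describe 3 libraries and the intervals cover counting error only.

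After cell calling, 6088 cells were kept from adipose tissue, 9281 from bone marrow and 3192 from blood. The libraries were of like total size, with 99356868, 106322567 and 98016815 UMIs. Kept cells held 95.5% of the UMIs in adipose tissue, 92.9% in bone marrow and 91.0% in blood. The median UMI count per cell was 14391 in adipose tissue, 9096 in bone marrow and 24884 in blood. The median number of genes per cell was 3612.5, 2795 and 4641 in the same order. When every cell was thinned to 3000 UMIs, the medians became 1427, 1391 and 1383 genes. Mitochondrial genes took a median of 2.94%, 2.47% and 2.45% of UMIs.

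Most cells in each culture expressed collagens and other genes of fibroblast-like stroma, and 3 smaller populations stood beside them. Bone marrow and blood cultures held macrophage-like cells, marked by genes of phagocytes such as the complement component C1QA, the integrin ITGAM, the lysozyme gene LYZ and the leukocyte phosphatase PTPRC. The adipose culture held a few endothelial-like cells with the selectins SELP and SELE, which let leukocytes roll on vessel walls, and the growth factor PDGFB. Bone marrow also held a cluster in which macrophage and stromal genes were read together.

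Stromal-like clusters made up 6026 of 6088 cells (98.98%) in adipose tissue, 8303 (89.5%, 95% interval 88.8 to 90.1%) in bone marrow and 2499 (78.3%, 76.8 to 79.7%) in blood. A further 538 blood cells (16.9%, 15.6 to 18.2%) formed a cluster led by ANKRD1, FST, BASP1, NES and SH3BGR. It reached 50 CPM for 14 of 16 stromal markers but stayed unnamed, since another class had more markers than stroma among its leading genes. Macrophage-like cells numbered 514 (5.54%, 5.08 to 6.02%) in bone marrow and 155 (4.86%, 4.14 to 5.66%) in blood. These shares depend on the UMI threshold for cells: barcodes with at least 1% macrophage-marker UMIs made up 5.61% of kept cells in bone marrow and 2.10% in blood, but 11.5% and 8.16% of all barcodes of at least 1000 UMIs. At a clustering resolution of 1.0, blood instead gave 76 macrophage-like cells (2.38%, 1.88 to 2.97%) and 81 mixed cells (2.54%). Adipose tissue gave no macrophage-like cluster, and 0 of its 6088 cells held at least 1% macrophage-marker UMIs, which allows a share of up to 0.0493% (3 counts of the total). The mixed cluster of bone marrow held 464 of 9281 cells (95% interval 4.56 to 5.46%), led by CCL3, RETN, MMP9, ENSBTAG00000037605 and BLA-DQB. Endothelial-like cells were 39 of the adipose cells (0.641%, 0.456 to 0.875%). SELE read 1248 CPM in them and 0.0953 CPM in the other adipose cells. No endothelial-like cluster was found in bone marrow or blood, which does not exclude scattered cells too few to form a cluster. The 23 cells of the last adipose cluster, led by ACTG2, CALCB (ENSBTAG00000047380), GSTM3, AKR1A1 and RPS26, were left unnamed.

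**Figure D1:**
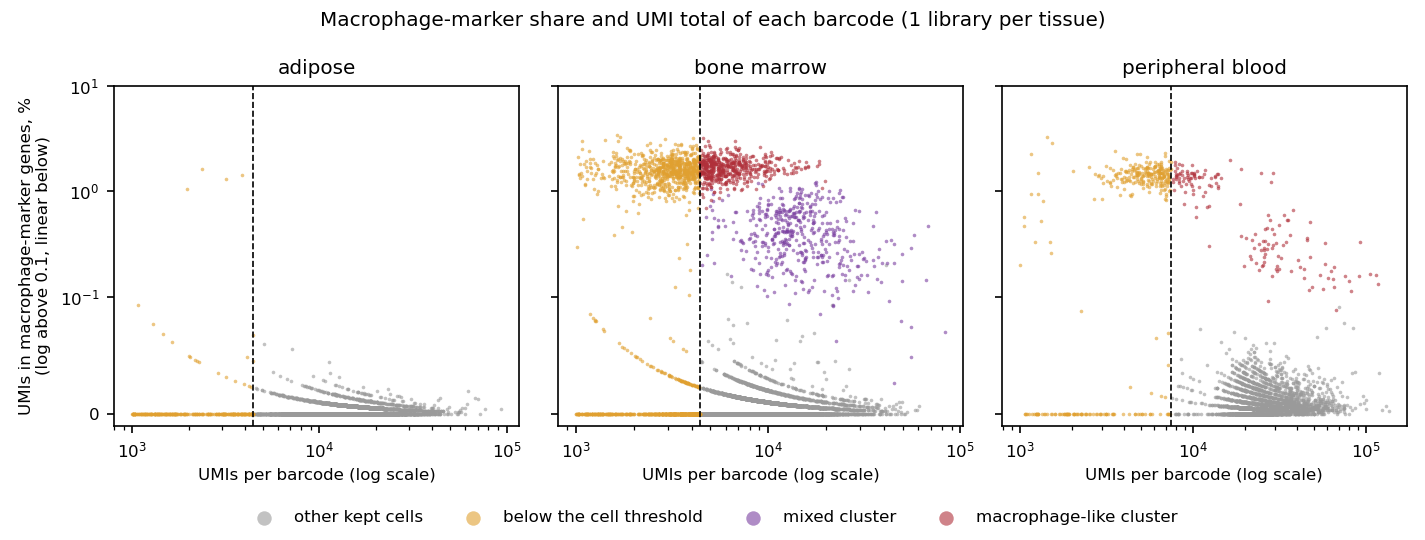
Each point is a barcode, with its UMI total on the horizontal axis (log scale) and the percent of its UMIs in macrophage-marker genes on the vertical axis (log scale above 0.1, linear below), 1 panel per tissue; the dashed line is the UMI threshold for cells, grey points are other kept cells, orange points lie below the threshold, purple points are the mixed cluster and red points the macrophage-like cluster. Barcodes with at least 1% macrophage-marker UMIs made up 5.61% of the kept cells in bone marrow, 2.10% in blood and 0 of 6088 in adipose tissue.

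In adipose tissue the leading genes of the stromal-like clusters were the histones H3C3, H2AC12, H2AC20, H3C7 and H1-4 in cluster 0, ASPN, ACTA2, SERPINF1, IFIT1 and CCN2 in cluster 1, ANKRD1, HJURP, FST, CDK1 and TOP2A in cluster 2, and the mitotic genes KNSTRN, CCNB1, PLK1, REEP4 and PIMREG in cluster 3. In bone marrow they were IGFBP5, TINAGL1, UNC13D, LIPG and INHBA in cluster 0, DDIT3, REEP4, H2BC15, CCNB1 and CENPA in cluster 1, SERPINF1, CLU, IFIT1, SORBS2 and ALDH1L2 in cluster 2, TOP2A, NUSAP1, CDCA8, UBE2C and AURKA in cluster 4, EDNRA, OMD, BMP2, DKK1 and ENPP1 in cluster 5, and H3C3, H3C7, H2AC12, H4C3 and H2AC20 in cluster 6. In blood they were CDKN2D, TOP2A, UBE2C, HJURP and KIF23 in cluster 1, MEOX1, ALDH1A1, MDFI, IGFBP5 and ADAMTS1 in cluster 2, CA4, ENSBTAG00000001911, INHBA, CXCL12 and CCL2 in cluster 3, LRRN4CL, ENSBTAG00000020097, TIMP3, ARF2 and MFAP5 in cluster 4, and ENSBTAG00000052665, ASPN, SST, IL6 and SFRP4 in cluster 5. The macrophage-like clusters were led by CCL8, FABP4, ENSBTAG00000010458, LYZ and FGR in bone marrow and by ITGAM, PTPRC, CYBB, RNASE6 and C1QA in blood. Genes leading the endothelial-like cells included SELP, PDGFB, SELE and EDN1.

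The surface markers used to define MSCs were not all read at like depth. ITGB1 and CD44, adhesion receptors of cultured stroma, were abundant in all 3 libraries, and NT5E and ENG were intermediate. THY1, a common positive marker in human MSCs, was near the limit of detection. The leukocyte marker PTPRC and the progenitor marker CD34, which MSCs should lack, were rare, PTPRC apart from the macrophage-like cells.

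ITGB1 read 674 CPM in adipose tissue, 788 in bone marrow and 715 in blood, and CD44 read 242, 236 and 210 CPM. NT5E read 51.4, 118 and 147 CPM, and ENG 56.5, 36.0 and 75.5 CPM. THY1 was at 3.12, 1.73 and 4.23 CPM. At 3000 UMIs per cell, a UMI of ITGB1 was found in 84.5%, 88.0% and 86.4% of the cells, and one of CD44 in 49.3%, 48.6% and 43.6%. NT5E was found in 13.4% (12.6 to 14.3%) of adipose cells, 27.1% (26.2 to 28.0%) of bone marrow cells and 32.1% (30.5 to 33.8%) of blood cells, and ENG in 15.2%, 9.86% and 20.4%. THY1 was found in 1.03% (0.796 to 1.32%), 0.474% (0.345 to 0.636%) and 1.22% (0.870 to 1.67%). In the macrophage-like cells of bone marrow and blood, whose median depths before thinning were 5895 and 20421 UMIs, THY1 was found in 0.195% and 0.645%, NT5E in 0.973% and 14.8%, ENG in 8.75% and 12.9%, ITGB1 in 50.6% and 65.8%, and CD44 in 81.1% and 33.5%. The blood figures include cells that were called mixed at the finer resolution. Free RNA held NT5E at 38.7, 83.1 and 82.0 CPM, ENG at 57.8, 27.7 and 68.5, and THY1 at 4.78, 0 and 6.02 in adipose tissue, bone marrow and blood. The level of ENG in adipose cells and of THY1 in adipose and blood cells did not exceed that in free RNA. This comparison alone cannot tell how much of these shares is background, since it leaves out the fraction of a cell's UMIs that is free RNA. Macrophage genes bound that fraction at 3.37% in blood. No bound was made for adipose tissue, so background stays open for the adipose shares. Without thinning, the shares were 99.4%, 98.3% and 99.8% for ITGB1, 92.1%, 84.4% and 97.4% for CD44, 47.1%, 59.2% and 88.0% for NT5E, 50.8%, 29.9% and 79.8% for ENG, and 4.55%, 1.77% and 10.0% for THY1.

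PTPRC was found at 3000 UMIs in 0 of 6088 adipose cells, 2.60% of bone marrow cells and 1.03% of blood cells. CD14 was found in 2.20%, 6.32% and 3.63%, and CD34 in 0.756%, 0 and 0.219%. In CPM, PTPRC read 0.0105, 8.65 and 2.58, CD14 read 8.09, 30.8 and 16.2, and CD34 read 2.35, 0.0506 and 0.976. The remaining cells, with median depths of 14403, 9108 and 24926 UMIs, gave PTPRC in 0, 0.0120% and 0.0329%. CD14 was found in 2.22%, 0.891% and 0.757% of the remaining cells. Free RNA held CD14 at 13.4, 52.3 and 34.2 CPM, above the level in the cells of each library. That comparison cannot tell how much of these shares is background, since it leaves out the fraction of a cell's UMIs that is free RNA. Macrophage genes bound that fraction at 1.54% in bone marrow and 3.37% in blood, and no bound was made for adipose tissue. Whether the remaining cells express CD14 was not settled. In the macrophage-like cells of bone marrow and blood, PTPRC was found in 35.4% and 20.6%, CD14 in 66.1% and 60.0%, the class II gene BOLA-DRA in 61.9% and 66.5%, and CD34 in 0 cells. Without thinning, PTPRC was found in 0.0164%, 5.60% and 3.70% of all cells, CD14 in 11.4%, 11.4% and 12.4%, and CD34 in 2.86%, 0.0539% and 2.60%. The 39 endothelial-like cells are part of the adipose value for CD34. Free RNA held PTPRC at 0, 8.47 and 0.753 CPM and CD34 at 0.955, 0 and 1.13 CPM. As for CD14, these levels alone cannot tell how much of the CD34 share in blood is background. For PTPRC in bone marrow, the remaining cells lay in the same free RNA and gave 0.0120%, against 35.4% of the macrophage-like cells. This argues against background as the main source of the PTPRC share over all bone marrow cells.

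Bone marrow cells, compared with adipose cells, read several genes linked to bone at much higher levels. These were SPP1 (osteopontin), the growth factor BMP2, the homeobox gene DLX5 that acts in osteoblasts and the bone proteoglycan osteomodulin (OMD). ENPP1, which acts on mineral deposition, was higher as well. So were GREM1 and DKK1, secreted antagonists of BMP and Wnt signals. Of 9 osteogenic-list genes measured, 4 were at least 2-fold higher in bone marrow and 1 in adipose tissue. Interleukin 6 was higher too, as were B2M and PSMB8, which act in class I presentation. Adipose cells read higher SFRP2, a Wnt modulator, IL1RL1, the receptor of interleukin 33, the activin binder FST, the proteoglycan VCAN and several HOX genes, which keep a record of position along the body. The genes of phagocytes and neutrophils that set bone marrow apart came mostly from its macrophage-like and mixed cells.

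By the 2-fold rule, 81 genes were higher in adipose tissue and 138 in bone marrow, 6.90% of the 3174 genes at or above 50 CPM. In the remaining cells the counts were 83 and 109, and 76 and 102 genes were counted in both. SPP1 (ENSBTAG00000005260) read 1403 CPM in bone marrow and 60.4 in adipose tissue, a 23.2-fold difference (22.6 to 23.9), or 18.2-fold in the remaining cells. BMP2 (ENSBTAG00000005111) read 179 and 3.48 CPM (51.5-fold, 46.2 to 57.6), and DLX5 (ENSBTAG00000018645) 64.6 and 0.158 CPM (408-fold, 247 to 729.9). OMD was 9.92-fold and ENPP1 23.6-fold higher. GREM1 (ENSBTAG00000050495) was at 108 CPM against 1.24 (86.7-fold, 72.3 to 105), and DKK1 at 85.7 CPM against 1.41 (60.7-fold). The netrin receptor gene UNC5B was 28.4-fold higher (47.5-fold in the remaining cells), MDFI 27.4-fold, WNT5B 19.9-fold and the homeobox gene BARX1 46.3-fold. IL6 (ENSBTAG00000014921) read 288 CPM in bone marrow and 6.21 in adipose tissue, a 46.4-fold difference (42.7 to 50.4).

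In the other direction, SFRP2 (ENSBTAG00000018563) read 114 CPM in adipose tissue and 0.526 in bone marrow (217-fold, 166 to 291). IL1RL1 (ENSBTAG00000018571) read 787 against 5.29 CPM (149-fold, 136 to 162), and LRRN4CL (ENSBTAG00000010484) 611 against 6.43 CPM (94.996-fold, 87.8 to 103). The factor FST was 14.9-fold higher in adipose tissue, VCAN 8.13-fold and TEX2 10.4-fold. UNC13D (ENSBTAG00000013556), LAMA4, TINAGL1 and AKAP12 were 5.55-fold, 5.31-fold, 5.19-fold and 4.59-fold higher. CSF1 (ENSBTAG00000000283), the growth factor of macrophages, read 1503 CPM in adipose tissue and 515 in bone marrow (2.92-fold, 2.89 to 2.95).

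Grouped by list, 4 of 9 osteogenic genes were at least 2-fold higher in bone marrow and 1 in adipose tissue, BMPR1B (3.85-fold), and the median log2 ratio of adipose tissue over bone marrow was −3.58. Of 7 class I genes, 2 were higher in bone marrow and 0 in adipose tissue, with a median of −1.38, or −0.86 in the remaining cells. B2M (ENSBTAG00000012330), the light chain of class I, was 2.60-fold higher in bone marrow, or 1.82-fold in the remaining cells, and PSMB8 (ENSBTAG00000003039) was 7.17-fold higher (6.72 to 7.66), or 6.42-fold in the remaining cells. The HOX genes had a median of 1.66, with 3 of 17 at least 2-fold higher in adipose tissue: HOXB7 10.4-fold, HOXC8 7.17-fold and HOXC6 3.15-fold. Of 27 patterning genes, EMX2 was 24.7-fold higher in adipose tissue, while BARX1 and IRX3 (3.33-fold) were higher in bone marrow, and the median was 0.48. Growth factors had a median of −0.41 and included FGF5 (35.9-fold) and PDGFA (68.5-fold) higher in bone marrow. Among BMP, TGF-beta and Wnt genes, 3 of 27 were higher in adipose tissue (SFRP2, FST and RSPO3, the last 4.42-fold) and 5 in bone marrow (BMP2, GREM1, DKK1, WNT5B and SMAD7, the last 2.24-fold), and the median of 0.09 did not stand apart, against −0.12 in G1-phase cells. Of 27 matrix glycoproteins, 4 were higher in adipose tissue (FBLN5 52.0-fold, THBS1 4.12-fold) and 5 in bone marrow (FMOD 4.72-fold, LUM 4.30-fold, FN1 3.69-fold). Their median was −0.13, and in G1-phase cells alone it was 0.11. The collagens had a median of −0.12, with COL8A1 12.04-fold higher in bone marrow, and 0.21 in G1-phase cells. Contractile genes had a median of −0.17, against 0.51 in G1-phase cells, with CNN1 5.92-fold higher in adipose tissue. G1-phase cells were taken from all kept cells, without removing macrophage-like ones. In the remaining cells the medians were −0.18 for matrix glycoproteins, −0.20 for collagens and −0.25 for contractile genes, on the same side as over all cells.

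Several medians between these libraries turned sign with the macrophage-like and mixed cells. Chemokines and inflammatory cytokines had a median of −0.42 in all cells and 0.41 in the remaining cells. CXCL8 was 3.07-fold higher in bone marrow over all cells but read 0.620 times the adipose level in the remaining cells, while CXCL12 was 3.34-fold higher in adipose tissue over all cells. Immunomodulatory factors had a median of −0.21 in all cells. In the remaining cells it was 0.10, within the central 95% of random lists (−0.14 to 0.25), so the list did not stand apart there. Over all cells, 2 of 13 were at least 2-fold higher in adipose tissue, LGALS3 (3.13-fold) and HMOX1 (3.32-fold). In bone marrow 3 were higher, IL6, NT5E and TGFB1 (95.1 against 45.3 CPM). Matrix remodelling genes had a median of −0.45 in all cells. In the remaining cells it was 0.069, which did not stand apart. With TMM factors it was slightly below 0 there, so its direction in those cells is not settled. MMP9 was at 111 CPM in bone marrow and 0.527 in adipose tissue, and at 4.72 and 0.530 CPM in the remaining cells. The adipogenic list had a median of −0.65, or −0.25 in the remaining cells. Of its members, FABP4 was at 99.6 CPM in bone marrow and 3.72 in adipose tissue, and at 4.93 and 0.328 in the remaining cells. The fatty acid carrier CD36 read 94.9 and 11.5 CPM, and 8.47 and 11.3 in the remaining cells. Monocyte and macrophage genes had a median of −8.78, neutrophil genes −12.76 and antimicrobial genes −12.26 over all cells, and too few members were measured in the remaining cells for a median. S100A12, a calcium-binding protein of neutrophils and monocytes, read 954 CPM in bone marrow against 0.137 in adipose tissue, and 26.8 CPM in the remaining bone marrow cells. S100A8 rested on 3 UMIs in adipose tissue, with a ratio of 8022 (2745 to 38902), or 150.9 (51.3 to 735) in the remaining cells. LYZ rested on 3 UMIs as well, with a ratio of 4847 (1658 to 23508), or 99.5 (33.7 to 486) in the remaining cells. TYROBP was 1937-fold and SRGN, which is expressed in blood cells, 537-fold higher in bone marrow over all cells. DEFB4A, a defensin, had 0 UMIs in adipose tissue. Set against 3 counts there, it was 5059-fold higher in bone marrow (exact interval from 4114, with no upper end), or 88.7-fold in the remaining cells. Free RNA in bone marrow held S100A8 at 829 CPM, LYZ at 323, DEFB4A at 436 and MMP9 at 306, and how much of the low levels in the remaining cells it gave was not settled. Interferon-response genes (−0.11) and senescence genes (−0.11) did not stand apart, although IFI6 was 13.2-fold higher in bone marrow, or 5.40-fold in the remaining cells. The medians were −0.23 for positive MSC markers, −0.43 for tenogenic genes, −0.12 for glycolysis, −0.32 for cholesterol synthesis and 0.21 for immediate early genes.

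**Figure D2:**
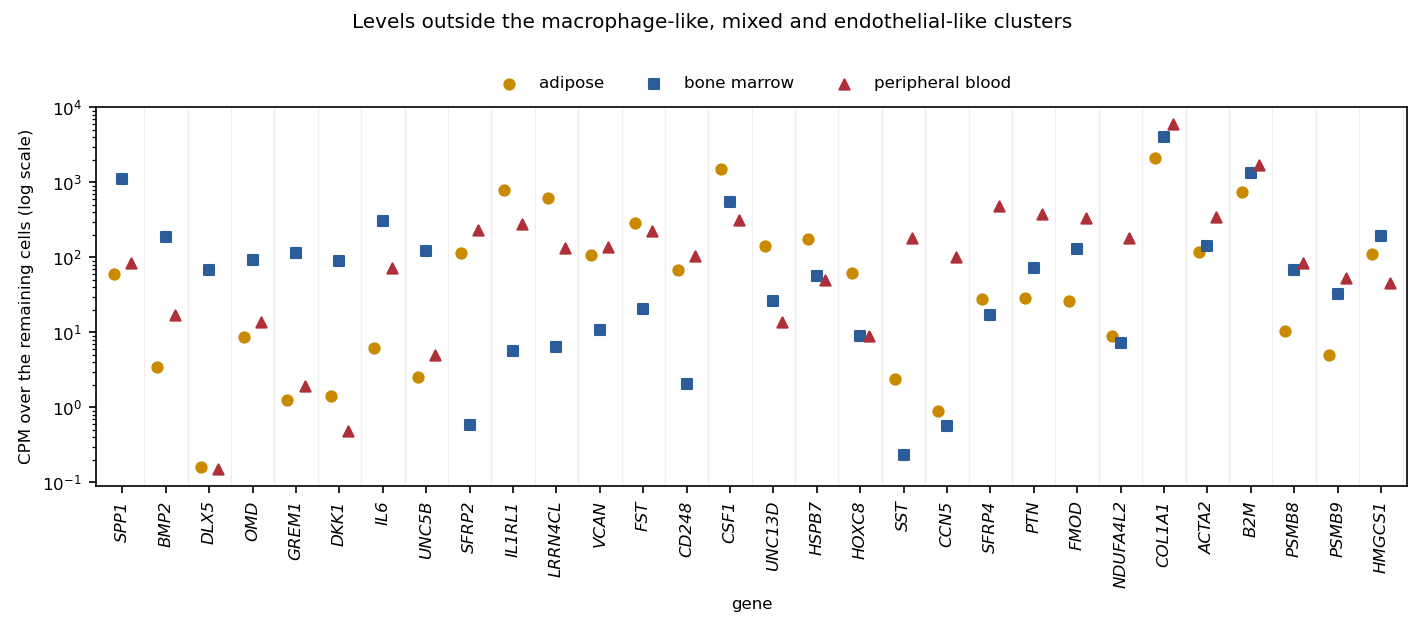
Levels of 30 genes in CPM (log scale) over the remaining cells of the adipose, bone marrow and blood libraries, with 1 point per gene and library and no replicates. SPP1 stood at 1105 CPM in bone marrow against 60.7 in adipose tissue and 83.8 in blood.

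Summed over its cells, the blood library read contractile and collagen genes higher than the adipose library. Clusters of these libraries overlapped in ACTA2 and COL1A1. Higher in blood were SST, the peptide hormone somatostatin, the matricellular gene CCN5, the Wnt modulator SFRP4, pleiotrophin (PTN), the protease HTRA3, and the smooth muscle genes ACTA2, MYL9 and TAGLN. Chemokines that recruit neutrophils (CXCL5, GRO1 and CXCL2) and the immunoproteasome genes PSMB8 and PSMB9 were higher in blood as well. Higher in adipose tissue were the Wnt amplifier RSPO3, the growth factor carrier IGFBP3, UNC13D, CSF1, DPT and HOXC genes.

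The 2-fold rule counted 38 genes higher in adipose tissue and 121 in blood, 5.03% of 3161 genes, and 40 and 119 in the remaining cells, with 38 and 113 counted in both. SST (ENSBTAG00000017312) read 181 CPM in blood and 2.40 in adipose tissue (75.3-fold, 66.1 to 86.2). CCN5 (ENSBTAG00000006037) read 100.5 against 0.886 CPM (113-fold, 91.5 to 142), and SFRP4 (ENSBTAG00000015366) 474 against 27.3 CPM (17.3-fold). NDUFA4L2, a hypoxia-responsive mitochondrial gene, was 19.98-fold higher in blood (18.7 to 21.4). PTN was 13.2-fold, HTRA3 8.38-fold and the integrin ITGA1 6.11-fold higher. MMP9 was at 116 CPM in blood and 0.527 in adipose tissue (221-fold, 167 to 297), and at 9.03 and 0.530 CPM in the remaining cells; free RNA in blood held 268 CPM of it. IL6 was 11.3-fold and FGF5 19.7-fold higher in blood. UNC13D was 10.3-fold higher in adipose tissue (9.70 to 10.9), IGFBP3 10.8-fold, DPT 7.51-fold and RSPO3 159-fold (113 to 231). CSF1 was 4.86-fold higher in adipose tissue (4.799 to 4.92), LRRN4CL 4.66-fold, FILIP1L 4.21-fold, HSPB7 3.596-fold and the histone H2AC20 3.66-fold.

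Of 12 contractile and pericyte genes, 6 were higher in blood and 0 in adipose tissue, with a median log2 ratio of adipose tissue over blood of −1.11. ACTA2 was 2.81-fold higher, MYL9 3.70-fold, TAGLN 2.68-fold and ACTG2 5.49-fold. Of 16 collagens, 3 were higher in blood, COL1A1 2.78-fold, COL3A1 2.16-fold and COL1A2 2.04-fold, and the median was −0.70. Of 29 matrix glycoproteins, 9 were higher in blood and 1 in adipose tissue, with a median of −0.75; FMOD was 12.6-fold higher (12.1 to 13.1), LUM 3.66-fold, BGN 3.49-fold and FN1 3.42-fold. The crosslinking enzymes LOXL2 and LOX were 2.99-fold and 2.80-fold higher in blood. Matrix remodelling genes had a median of −0.45, with SERPINE2 3.98-fold and TIMP3 2.87-fold higher in blood, and tenogenic genes one of −0.69. Class I genes had a median of −1.50, with 3 of 8 higher in blood: B2M 2.52-fold, PSMB8 8.24-fold and PSMB9 (ENSBTAG00000008954) 10.6-fold. Interferon-response genes had a median of −1.38, with IFIT1 2.99-fold higher and IFI6 13.6-fold, or 5.47-fold in the remaining cells. Chemokines and cytokines had a median of −1.27, with CXCL5 2.42-fold and CXCL2 17.1-fold higher in blood. GRO1, a CXC chemokine outside the list, was 6.104-fold higher in blood. CXCL8 was 3.76-fold higher in blood, or 1.85-fold in the remaining cells. HOX genes had a median of 1.01, with HOXC8 6.84-fold and HOXC6 4.10-fold higher in adipose tissue. Cholesterol synthesis had a median of 0.74, with HMGCS1 2.44-fold higher in adipose tissue. The medians were −0.62 for osteogenic genes, −0.95 for adipogenic genes, −0.58 for positive MSC markers, −0.48 for senescence genes and for BMP, TGF-beta and Wnt genes, −0.24 for growth factors, 0.43 for patterning genes, −0.30 for glycolysis and −0.19 for immediate early genes. Monocyte and macrophage genes had a median of −4.71, or −2.20 in the remaining cells. Immunomodulatory factors (0.12) did not stand apart.

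**Figure D3:**
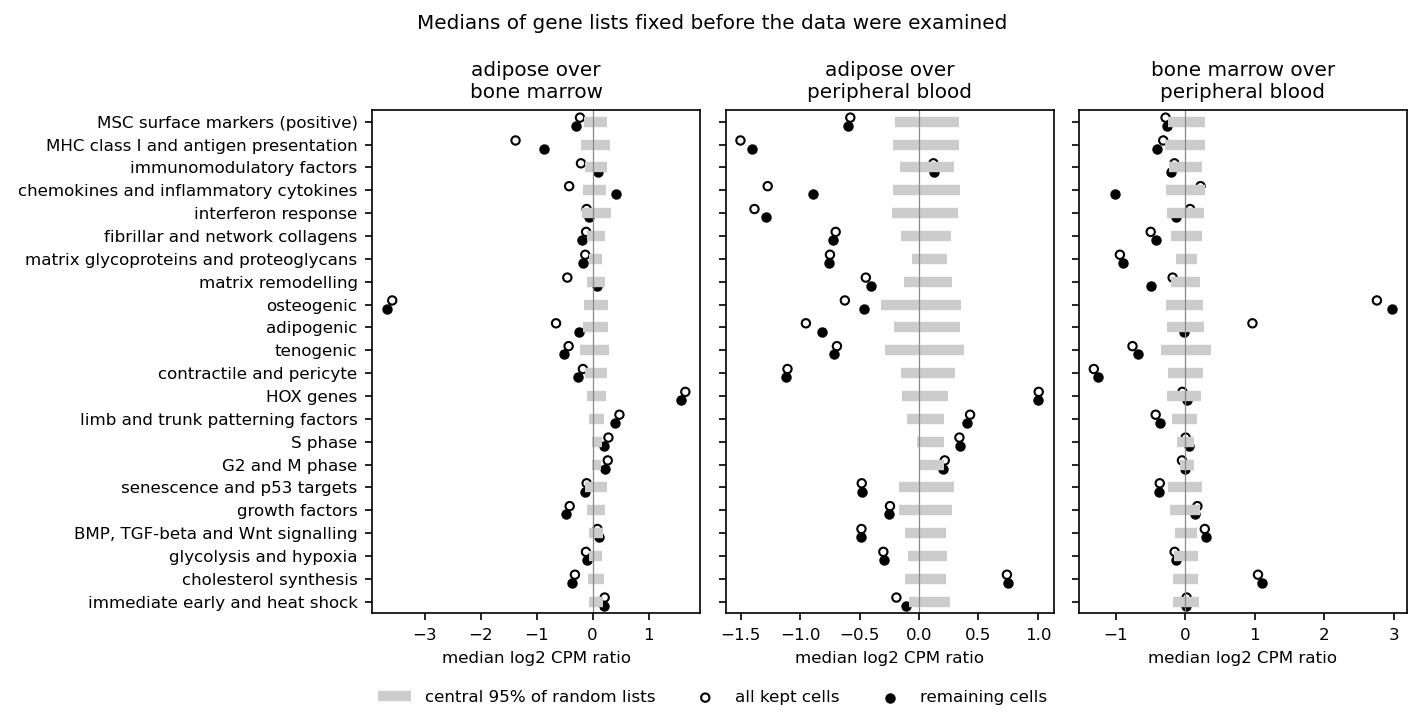
Median log2 CPM ratio (horizontal axis) of 22 gene lists, in 1 panel each for adipose tissue over bone marrow, adipose tissue over blood and bone marrow over blood; open points are all kept cells, filled points the remaining cells, and grey bars the central 95% of random lists for the remaining cells. The osteogenic median stood at −3.68 for adipose tissue over bone marrow and at 2.97 for bone marrow over blood in the remaining cells.

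Against blood, the bone marrow library again read SPP1, BMP2, DLX5, OMD, ENPP1, GREM1 and DKK1 higher. Enzymes that make cholesterol, such as HMGCS1 and SQLE, were higher in bone marrow, as were the neural and progenitor filament NES and the urokinase receptor PLAUR. The blood library read higher SFRP2, SFRP4, SST and CCN5, contractile genes and matrix glycoproteins.

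The 2-fold rule counted 121 genes higher in bone marrow and 122 in blood, 7.76% of 3131 genes, and 103 and 127 in the remaining cells, with 94 and 116 counted in both. SPP1 was 7.06-fold higher in bone marrow, or 13.2-fold in the remaining cells, BMP2 10.7-fold and DLX5 443-fold (259 to 832). GREM1 was 57.6-fold (49.4 to 67.5), DKK1 182-fold and UNC5B 23.8-fold higher. ENPP1 was 10.0-fold higher, or 15.02-fold in the remaining cells, and OMD 6.44-fold. BARX1 was 16.5-fold, IRX3 8.13-fold, NES 7.21-fold, PDGFA 11.9-fold, IGFBP3 11.7-fold, DPT 12.6-fold, PLAUR 4.84-fold and IL6 4.11-fold higher. SST was 852-fold higher in blood (557 to 1377, on 21 UMIs in bone marrow), SFRP2 431-fold (329 to 578) and CCN5 195-fold (148 to 262). IL1RL1 was 51.8-fold, CD248 52.5-fold, SFRP4 29.6-fold, NDUFA4L2 26.9-fold, HTRA3 26.7-fold and LRRN4CL 20.4-fold higher in blood.

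Of 10 osteogenic genes, 4 were at least 2-fold higher in bone marrow and 0 in blood, with a median log2 ratio of bone marrow over blood of 2.75. Of 20 cholesterol synthesis genes, 6 were higher in bone marrow and 0 in blood, with a median of 1.04: HMGCS1 4.10-fold, SQLE 3.59-fold, IDI1 3.29-fold, MSMO1 2.57-fold, FDPS 2.25-fold and CYP51A1 2.09-fold. Of 30 matrix glycoproteins, 10 were higher in blood and 1 in bone marrow, with a median of −0.94; VCAN was 10.2-fold, FBLN5 23.0-fold and FMOD 2.67-fold higher in blood. The laminin gene LAMA4, outside the list, was 7.03-fold higher in blood. Of 11 contractile genes, 4 were higher in blood and 0 in bone marrow, with a median of −1.31, ACTG2 40.7-fold, TAGLN 3.33-fold and MYL9 2.56-fold. Collagens had a median of −0.50, with COL3A1 3.48-fold and COL14A1 4.81-fold higher in blood, and tenogenic genes one of −0.76. Patterning genes had a median of −0.43, with EMX2 12.8-fold and NR2F1 8.76-fold higher in blood. BMP, TGF-beta and Wnt genes had a median of 0.28, with 4 of 27 higher in bone marrow and 5 in blood. Chemokines had a median of 0.22 in all cells, which did not stand apart, and −1.02 in the remaining cells, which did. CXCL5 was 2.56-fold higher in blood and CXCL2 2.55-fold, or 5.11-fold in the remaining cells. GRO1 was 3.79-fold higher in blood, or 9.16-fold in the remaining cells. The adipogenic median was 0.96 in all cells and −0.023 in the remaining cells, where it did not stand apart. Neutrophil genes had a median of 6.62, antimicrobial genes 6.15 and monocyte and macrophage genes 1.63 over all cells, and too few members of the 3 lists were measured in the remaining cells for a median. The medians were −0.32 for class I genes, −0.28 for positive MSC markers, 0.93 for the negative panel (over all cells, 3 members measured, and 0 in the remaining cells) and −0.37 for senescence genes. Matrix remodelling genes did not stand apart in all cells (−0.18) but did in the remaining cells (−0.49). Class II genes (0.20), interferon-response genes (0.07), HOX genes (−0.04), growth factors (0.17), immunomodulatory factors (−0.16), glycolysis (−0.15) and immediate early genes (0.02) did not stand apart.

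Pearson's r of log2 CPM, with a small constant added, was taken over genes of at least 50 CPM in either library of a pair. Genes are not independent replicates. The value was 0.839 between adipose tissue and bone marrow, 0.913 between adipose tissue and blood and 0.875 between bone marrow and blood. In the remaining cells it was 0.881, 0.918 and 0.885. Over both other libraries at once, 22 genes were at least 2-fold higher in adipose tissue, 73 in bone marrow and 46 in blood. In the remaining cells the counts were 25, 52 and 53. Genes of this kind in adipose tissue included UNC13D, RSPO3, HOXC8, HOXC6, ALDH1A1 (136 CPM against 29.7 in bone marrow and 43.8 in blood), ADM (157 against 45.4 and 60.4), ASRGL1 (254 against 108 and 108) and INHBA (335 against 148 and 142). In bone marrow they included DLX5, GREM1, DKK1, BMP2 and SPP1, and in blood SST, CCN5, SFRP4, NDUFA4L2, PTN and PRRX2 (2267 CPM against 692 and 1085).

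Transcripts of the proliferation genes TOP2A and MKI67 were read in all 3 cultures. At 3000 UMIs, a UMI of either was found in 66.7% (65.5 to 67.8%) of adipose cells, 55.4% (54.4 to 56.4%) of bone marrow cells and 53.4% (51.6 to 55.1%) of blood cells. In the remaining cells the shares were 66.8%, 58.2% and 54.2%, and in the macrophage-like cells 10.1% (7.65 to 13.1%) in bone marrow and 38.1% (30.4 to 46.2%) in blood, where mixed cells are included. Free RNA held both genes, TOP2A at 192, 188 and 154 CPM against 344, 291 and 318 in the cells. Macrophage genes bound free RNA at 1.54% of UMIs in bone marrow and 3.37% in blood. At those bounds it argues against free RNA as the main source of TOP2A there, and no bound was made for adipose tissue. A UMI of either gene does not by itself show a dividing cell, so these are not read as shares of dividing cells. Between stromal-like and unnamed clusters of at least 100 cells, TOP2A ranged from 41.4 to 539 CPM in adipose tissue, 36.2 to 640.3 in bone marrow and 37.0 to 594 in blood. The summed level of the S-phase list was 2924, 2407 and 2302 CPM, and that of the G2 and M list 7778, 6450 and 6678 CPM. Median log2 ratios of adipose tissue over bone marrow were 0.28 for S phase and 0.27 for G2 and M, the latter −0.063 in G1-phase cells. Over blood they were 0.34 and 0.22, and the latter did not stand apart in the remaining cells (0.20). Phase calls put 84.5%, 69.4% and 69.6% of the cells in S or G2/M, which are not read as cycling by themselves, since these shares moved with the thinning depth. For bone marrow over blood, the S-phase (0.00) and G2 and M (−0.05) medians did not stand apart. In G1-phase cells the latter was 0.61. G1-phase cells were chosen by low scores on these same lists, so their G2 and M medians (−0.063 and 0.61) say nothing about proliferation.

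Lists with too few measured members for a median in at least 1 pair are given as summed CPM in adipose tissue, bone marrow and blood. Complement genes summed to 95.1, 70.1 and 115 CPM, with C1QTNF1 the highest. Chondrogenic genes summed to 5.70, 61.2 and 45.2 CPM, of which COL11A1 gave 49.1 CPM in bone marrow and 30.0 in blood. Neural crest and Schwann cell genes summed to 197, 606 and 91.5 CPM, nearly all from NES (187, 588 and 81.6 CPM). Pluripotency genes summed to 84.6, 95.3 and 123 CPM, of which MYC gave 51.0, 68.0 and 55.1 CPM and KLF4 33.5, 27.3 and 67.7. Endothelial genes summed to 29.0, 7.46 and 12.7 CPM, and to 14.2, 2.36 and 12.6 in the remaining cells. Class II genes summed to 3.1, 76.1 and 62.3 CPM, and to 3.09, 5.21 and 7.06 in the remaining cells. The negative MSC panel summed to 10.5, 79.7 and 49.5 CPM, and to 9.70, 4.01 and 5.63 in the remaining cells. Neutrophil genes, which have no median for adipose tissue over blood, summed to 1.92, 1421 and 15.5 CPM, and to 0.403, 36.0 and 3.65 in the remaining cells. Antimicrobial genes summed to 5.58, 639 and 16.3 CPM, and to 4.44, 21.2 and 8.05 in the remaining cells. Lymphocyte genes summed to 1.68, 48.4 and 10.5 CPM, and to 1.66, 2.67 and 2.66 in the remaining cells. Erythroid genes summed to 0.928, 1.15 and 1.85, epithelial and mesothelial genes to 0.981, 2.11 and 2.16 (0.985, 0.594 and 2.04 in the remaining cells), and skeletal muscle genes to 3.22, 3.90 and 1.27.

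Several differences between libraries held across clusters. Among stromal-like and unnamed clusters of at least 100 cells, PSMB8 ranged from 9.57 to 11.5 CPM in adipose tissue, 64.8 to 74.4 in bone marrow and 58.8 to 112 in blood. IL6 ranged from 3.997 to 9.38, 222 to 466 and 11.7 to 142 CPM. GREM1 ranged from 0.698 to 2.10, 96.6 to 148 and 0.175 to 4.33 CPM. HOXC8 ranged from 54.6 to 70.0, 7.61 to 15.3 and 1.84 to 13.999 CPM. SST differed within blood, from 8.59 to 383 CPM. Other genes overlapped between clusters of adipose tissue and blood. COL1A1 ranged from 1333 to 3348 and from 2818 to 8255 CPM, and ACTA2 from 36.4 to 251 and from 131 to 452. CXCL5 ranged from 568 to 1150 and 762 to 3051, and SFRP4 from 21.9 to 35.0 and 26.2 to 925. LRRN4CL ranged from 531 to 701 and 18.4 to 547. HMGCS1 overlapped between bone marrow (105 to 297) and blood (26.9 to 106). Clusters of 1 culture are not replicates.

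**Figure D4:**
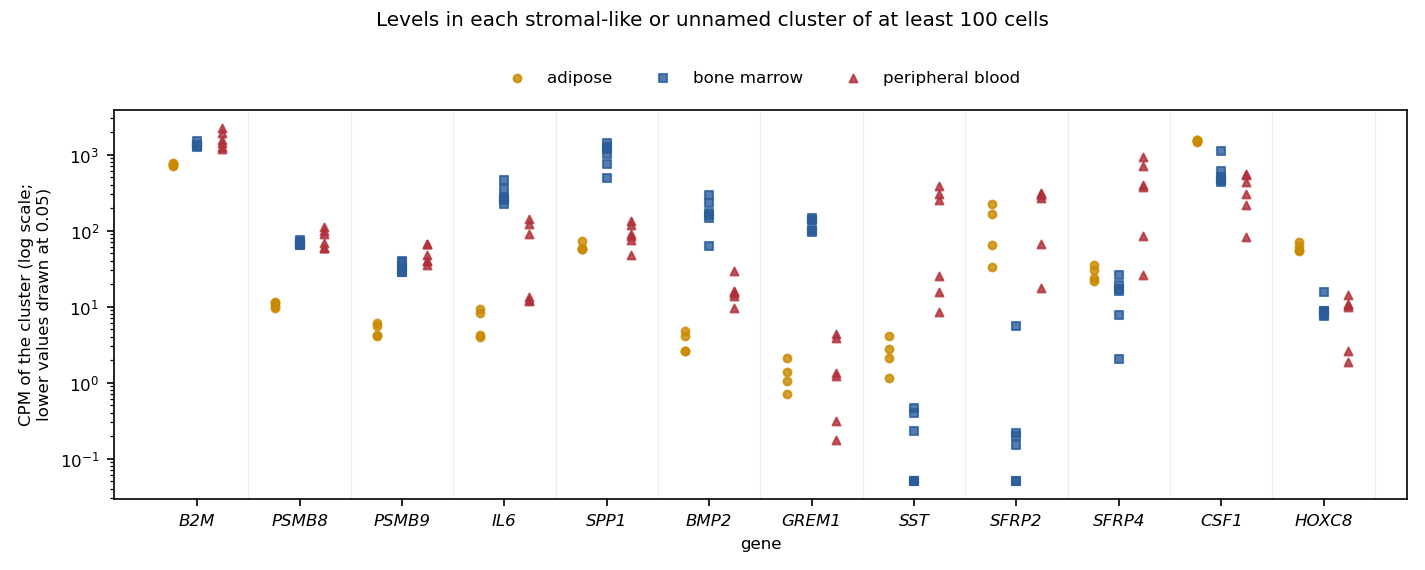
Levels in CPM (log scale, values below 0.05 drawn at 0.05) of 12 genes, with 1 point per stromal-like or unnamed cluster of at least 100 cells (4 in adipose tissue, 6 in bone marrow and 6 in blood). SPP1 lay between 491 and 1411 CPM in the bone marrow clusters, above all clusters of adipose tissue (56.4 to 73.0) and blood (48.2 to 132).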

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

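All tests in this part were chosen only after the result was seen. Barcodes under the UMI threshold for cells are not among the kept cells on which the tissues were compared, apart from an alternative that took all barcodes of at least 1000 UMIs. Among those of at least 1000 UMIs many carried macrophage genes. At least 1% macrophage-marker UMIs was found in 706 of 1417 such barcodes in bone marrow (49.8%, exact 95% interval 47.2 to 52.5%), in 221 of 338 in blood (65.4%, 60.0 to 70.4%) and in 4 of 295 in adipose tissue (1.36%, 0.371 to 3.44%). They drew attention as a signal in barcodes outside the kept cells, far above the level in the kept cells (5.61%, 2.10% and 0). The limit of 1% is a line through a range: 103 barcodes under the threshold in bone marrow and 42 in blood lay between 0.8 and 1.2%. The UMI threshold therefore leaves out many small macrophage-like barcodes, and no biological explanation was tested.

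The 464 mixed barcodes of bone marrow read macrophage and stromal genes together. Random loading of a macrophage and another cell into 1 droplet predicted 162 such barcodes (137 to 187), and the observed number was 2.87 times that, which argues against random loading as the whole cause. Free RNA cannot lift a gene above its level in free RNA itself, but 68 of 84 macrophage genes (81.0%) read higher in the mixed barcodes than in the empty droplets by the counting interval (median 1.81 times), which argues against free RNA as the whole cause. The median UMI count of the mixed barcodes was 1.08 times the sum of the medians of both kinds of cell, 0 genes stood over 2-fold above both kinds, and 84 macrophage genes were diluted alike (median 0.267, 5th to 95th percentile 0.197 to 0.354), so 2 whole cells under 1 barcode may be the source. Cells that adhered to each other and cells that engulfed others were not separated by these values.

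In blood, the 81 mixed barcodes at resolution 1.0 were 7.66 times the 10.6 expected from random loading (5 to 17). That expectation takes 85237 barcodes as the droplets, and 11128 droplets would be needed to give all 81. Of 84 macrophage genes with at least 10 UMIs in the empty droplets, 84 (100%) read higher in the mixed barcodes than in the empty droplets (median 4.25 times), which argues against free RNA. Their median UMI count was 0.991 times the sum of both kinds. The macrophage genes were diluted to a median of 0.183 over 86 genes (0.133 to 0.239), so the same explanation, 2 whole cells under 1 barcode, may hold there, with the same limit.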

How the results depend on the processing

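The alternatives without macrophage-like, mixed and endothelial-like clusters (the remaining cells), without the highest 6% of doublet scores, and the macrophage share over all barcodes of at least 1000 UMIs were chosen only after the result was seen. With 1 library per tissue none of these alternatives measures the variation between animals or cultures, and depth limits genes near the minimum of 50 CPM. No paired analysis was possible because the groups share only 1 replicate number and no test was made.

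Of the list medians, 807 kept their side of the central 95%, 20 of them with a turned sign but standing apart in neither case. A further 20 came to stand apart, 26 ceased to, and 23 that stood apart before or after turned sign. Of the log2 ratios of named genes, 3291 stayed within their counting interval, 1836 moved beyond it, 42 of them with a turned sign, and 21 of ratios at least 2-fold apart turned sign. Of the shares of cells with a UMI, which depend on the depth to which cells are thinned, 44 moved beyond their interval and 4 did not. The number of cells kept stayed within 1.5 times the reported number in 12 of 12 cases, and 108 of the counts of genes at least 2-fold apart did likewise. TMM factors over all cells moved no list median across its limit. Keeping doublet calls (0 were made) and the 10% mitochondrial limit (5, 0 and 1 cells removed) change almost nothing in the data and say nothing about stability. List medians were not rerun under the minimum of 10 CPM or of 4 UMIs.

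With a minimum of 10 CPM, the genes at least 2-fold apart numbered 232 for adipose tissue over bone marrow, 388 in reverse, 118 for adipose tissue over blood, 340 in reverse, 298 for bone marrow over blood and 306 in reverse, and 66, 202 and 116 for adipose tissue, bone marrow and blood over both others. With no minimum but 4 UMIs they numbered 1254, 1871, 973, 1641, 1562, 1301, 485, 1035 and 499, since more genes enter.

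With stromal-like clusters alone, the medians of adipose tissue over bone marrow turned to 0.10 for immunomodulatory factors, 0.41 for chemokines and 0.072 for matrix remodelling, and those of bone marrow over blood to −0.075 for adipogenic genes and −1.11 for chemokines. With the remaining cells they were 0.10, 0.41, 0.069, −0.023 and −1.02 in the same order. Of these, 0.10, 0.069 and −0.023 did not stand apart. With TMM factors as well they were 0.022 for immunomodulatory factors and 0.34 for chemokines. For bone marrow over blood they were then −0.022 for adipogenic genes and −1.02 for chemokines. Matrix remodelling stood slightly below 0 with TMM factors, its original side, and no longer apart. In G1-phase cells, adipose tissue over bone marrow turned to 0.10 for immunomodulatory factors, 0.21 for collagens and 0.11 for matrix glycoproteins. It turned to 0.51 for contractile genes and −0.12 for BMP, TGF-beta and Wnt genes. The G2 and M median turned to −0.063 there and to 0.61 for bone marrow over blood. Both G2 and M values are set by the choice of cells, which used that list. G1-phase cells were taken from all kept cells, without removing macrophage-like ones. Over all barcodes of at least 1000 UMIs the BMP, TGF-beta and Wnt median of adipose tissue over bone marrow turned to −0.089, and with each cell thinned to 3000 UMIs the chemokine median of bone marrow over blood to −0.47; the cause was not tested.

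Under stromal-like clusters alone, the remaining cells, and these with TMM factors, the log2 ratio of adipose tissue over bone marrow turned to 1.38, 1.38 and 1.31 for CD14, 0.42, 0.42 and 0.35 for CD36, 0.26, 0.26 and 0.18 for CTSB and 0.69, 0.69 and 0.62 for CXCL8. That of bone marrow over blood turned to −0.39, −0.35 and −0.34 for CTSB, −0.75, −0.74 and −0.74 for CTSS and −1.90, −2.00 and −2.00 for FABP4. These alternatives take away the macrophage-like cells by construction.

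Cells with an S or G2/M call in adipose tissue were 87.4% at 6000 UMIs and 88.3% without thinning. In bone marrow they were 63.6% at 1500, 70.6% at 6000 and 74.2% without thinning, and in blood 65.7% at 1500 and 73.7% without thinning. Over all barcodes of at least 1000 UMIs, 0.0627%, 11.5% and 8.16% were rich in macrophage UMIs in adipose tissue, bone marrow and blood. At resolution 1.0, stromal-like cells made up 80.9%, 86.1% and 63.2% and macrophage-like cells 2.38% in blood, and at resolution 0.2 stromal-like cells made up 95.1% in blood; the cause was not tested.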

Other observations

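All tests in this part were chosen only after the result was seen. The macrophage-like cells of bone marrow and blood were not alike. In bone marrow they read the calgranulins S100A8, S100A9 and S100A12, lysozyme and the fatty acid carriers FABP4, FABP5 and CD36 higher. In blood they read the inflammatory cytokines TNF, IL1A and IL1B, the class II genes BOLA-DRA, CD74 and BOLA-DMB, the protease MMP9 and the interferon-induced gene IFI6 higher. Both read SPP1 and the scavenger receptor CD163.

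Bone marrow is given by its 514 cells (median 5895 UMIs) and blood by the 76 macrophage-like cells of resolution 1.0 (9862 UMIs). The UMI thresholds for cells were unlike, at 4414 in bone marrow and 7489 in blood. Under them, 706 barcodes in bone marrow and 221 in blood held at least 1% macrophage-marker UMIs and are left out here. The values therefore describe the larger macrophage-like barcodes of each library. S100A12 read 17586 CPM in bone marrow and 409 in blood (43.0-fold), S100A8 4750 and 17.4 (272-fold) and LYZ 3043 and 120 (25.4-fold). FABP4 rested on 2 UMIs in blood, with a ratio of 908 (251 to 7502). FABP5 read 4189 and 1171 CPM, and CD36 1689 and 464. TNF read 3.47 CPM in bone marrow and 137 in blood, IL1A 22.9 and 322, and IL1B 59.9 and 252. BOLA-DRA read 562 and 1541 CPM, CD74 450 and 1496, MMP9 1615 and 5740, and IFI6 1016 and 3813. SPP1 read 6084 and 7588 CPM, and CD163 331 and 621. By the 2-fold rule, 4 of 4 neutrophil-list genes at 50 CPM were higher in bone marrow, while 4 of 6 class II genes and 6 of 10 chemokine and cytokine genes were higher in blood. Of the chemokine and cytokine genes, CXCL16 was higher in bone marrow (4.02-fold). Other lists split both ways between bone marrow and blood: 3 and 3 of 12 matrix remodelling genes, 2 and 2 of 19 monocyte and macrophage genes, and 3 and 2 of 7 adipogenic genes.

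The 23 cells of the unnamed adipose cluster held a median of 0.0411% mitochondrial UMIs and 34.7% ribosomal protein UMIs, at a median of 6909 UMIs per cell. The 6088 adipose cells together held medians of 2.94% and 22.4%.

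In the remaining cells, B2M, PSMB8 and PSMB9 were higher in bone marrow and blood, the cultures with macrophage-like cells, than in adipose tissue (1.82-fold, 6.42-fold and 6.37-fold in bone marrow and 2.27-fold, 8.03-fold and 10.4-fold in blood). Free macrophage RNA, at its upper bound of 1.54% of UMIs in bone marrow and 3.37% in blood, gives at most 7.78% and 5.74% of the excess of any of the 3 genes, which argues against it as the whole cause. TAP1 was higher as well, at 32.0 CPM in bone marrow and 22.0 in blood against 7.15. PSMB10 was nearly level in bone marrow (21.6 against 20.3 CPM) and read 32.5 CPM in blood. For PSMB10, free RNA at its bound gives 31.3% and 16.1% of the excess. Macrophages could act on the stromal cells, for example by cytokines, but their share of 5.61% in bone marrow and 2.10% in blood cannot be told apart from the tissue itself, since each tissue has 1 library. A difference between the tissues of origin also stays open and untested.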
